A study of Mus musculus with 40 samples.

How the data were processed

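Expression of a panel of 200 genes was measured in forebrain RNA of 40 mice with the NanoString nCounter, which hybridises a fluorescent barcode to each transcript and counts the barcodes without amplification. Per the labels, cortex and hippocampus were dissected together from male C57BL/6 mice, frozen and homogenised, and total RNA was purified from the whole lysate. The mice form 4 groups of 10, and each sample is a separate animal. MeCP2 knockout (KO) mice had wild-type (WT) littermates, here called KO-line WT, and both groups were 8 weeks old. Mice with the R306C change in MeCP2 had their own WT littermates, here called R306C-line WT, and were 8 to 12 weeks old. The group and number of every sample came from its label.

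The deposited table holds normalized barcode counts, treated here as a signal with no negative values, for the 200 genes, 6 positive-control probes and 8 negative-control probes. The steps by which the authors normalized the values are not given in the sources used here and were read from the values. In every library 100% of gene values were whole multiples of a single step, within a tolerance of 0.0055, while control probes held whole numbers. The geometric mean of 6 genes (Aars, Asb7, Ccdc127, Csnk2a2, Lars and Tada2b) was 565.2 in every library of the KO cohort and 458.6 in every library of the R306C cohort. The scale of the deposited values thus differed between cohorts by a log2 ratio of -0.30, which cancels in each mutant against its own WT. No count test was run, because it was planned for a table of raw counts and the gene values here are scaled, beside raw control probes. Whole numbers recovered through the step were used for depth and were not tested.

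Depth was taken as the sum over genes of values divided by that step, and ranged from 52290 to 154157 barcodes per library with a median of 99746. Background was set in each library at the mean plus 2 SD of the negative controls, on the scale of the gene values. By this measure 179 genes were above background in all 40 libraries and 7 were above it in fewer than 20 libraries. No gene was removed. The number of barcodes limits the precision of genes with low values, and with 10 mice per group the errors given cover differences between animals.

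Values were tested as log2(value + 1), so fold changes are on that scale and understate the change of genes with low values. One model with 4 group means was fitted to all 40 libraries with limma (lmFit and eBayes, version 3.58.1, in R 4.3.3), so that the groups share an estimate of the spread. P-values were two-sided and adjusted with Benjamini-Hochberg over 200 genes, and a gene was called at an adjusted p under 0.05. Contrasts were KO against KO-line WT, R306C against R306C-line WT, the difference between these 2 changes, and, as a check, the WT groups against each other. In simulated data for KO against KO-line WT with 80 of 200 genes changed, over 20 sets, limma recovered 45.1% of genes changed by a log2 of 0.2 and 89.1% of those changed by 0.4, and 2.98% of calls were false. The simulated noise was drawn separately for each gene and library. The real libraries share structure that it lacks, so these rates describe the simulation and not the real calls.

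Gene lists were fixed before the data were examined. Lists with at least 5 measured members were tested with limma's camera against the rest of the panel, with a preset correlation of 0.01 and with an estimated correlation beside it, adjusted over lists. The tested lists were reference genes, cell adhesion and synapse organisers, axon guidance and Eph receptors, ion channels, neurotransmitter receptors, genes studied earlier in MeCP2 mutants, signalling enzymes, and transcription and chromatin regulators. Inhibitory neuron markers had 3 members, excitatory neuron markers 1 and oligodendrocyte markers 1, which are given as values. The fixed lists of activity-regulated genes and of markers of astrocytes, microglia, endothelial and mural cells, and striatum and choroid plexus had 0 measured members, which does not exclude other genes of these cells on the panel. The list of signalling enzymes was made with symbol patterns and took in Adcyap1, which encodes a neuropeptide. MeCP2 was left out of list and length tests.

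The genes named for each mutant were fixed by rule: MeCP2, the 12 largest rises and the 12 largest falls among called genes, and up to 4 members of each list with the largest absolute change. For the difference, up to 10 called genes with the lowest adjusted p were named. Gene names were matched to a RefSeq table of assembly GRCm38.p6: 191 matched as symbols, 1 ignoring case and 6 as synonyms, and 2 unmatched names were kept as given. The same table gave the genomic span of 198 genes, used as gene length. The files name no genome build, so no coordinates are given.

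Correlations across genes and with length were set against 100 permutations of genotype labels within each cohort, for which 0.0099 is the smallest p. Permuted labels still hold part of the genotype effect, so residuals from the group means were also permuted, a check chosen after seeing the data. Alternatives were other pseudocounts, a filter on the genes with the lowest means, 3 other scalings, each cohort fitted alone, the replicate number as a block, sample weights with robust variances, a rank-sum test, stricter thresholds, other length limits and each sample left out. The set of replicates in the R306C cohort, correlations without MeCP2 and a common scale for both cohorts were added after the data were received. Statmod 1.5.0 and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were also used.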

Results

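Normalized counts of 200 genes were obtained from the forebrain of 10 KO mice, 10 KO-line WT littermates, 10 R306C mice and 10 R306C-line WT littermates. MeCP2 is a nuclear protein that binds methylated DNA, and mutations in its X-linked gene cause Rett syndrome. The KO removes the protein, and R306C is a missense change, found in Rett syndrome, in the part of MeCP2 that binds the NCoR/SMRT co-repressor. The series' title concerns repression of highly methylated long genes by MeCP2, and the design sets each mutant against its own WT littermates. How the panel was chosen is not given in the sources used here, so counts of changed genes describe this panel and not the genome. The median depth was 107371 barcodes per library in KO-line WT, 100725 in KO, 84510 in R306C-line WT and 98086.5 in R306C.

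MeCP2 itself was at 212 ± 13.5 normalized counts in KO-line WT (SD, n = 10; range 188.55 to 225.39) and at 7.06 ± 2.32 in KO (range 4.14 to 12.37). No KO library was above background for MeCP2, and KO-line WT was at least 9.04-fold higher than the mean background of the KO libraries (limma, adjusted p = 3.1e-35). In R306C the transcript was present in all 10 mice, at 187 ± 25.0 against 171 ± 19.9 in R306C-line WT, a log2 change of 0.13 ± 0.10 (SE) that did not pass the test (adjusted p = 0.26).

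Loss of MeCP2 moved most of the panel in both directions: 95 genes rose and 85 fell in KO, and 20 were not called. Bmper, a secreted regulator of bone morphogenetic proteins, rose most, from 202 ± 26.8 to 328 ± 45.5 normalized counts (1.61-fold; log2 0.69 ± 0.10 SE, adjusted p = 1.7e-07, 10 of 10 KO mice above the WT mean). After MeCP2, Abca8a, an ABC-family membrane transporter, fell most, from 58.9 ± 10.7 to 30.3 ± 3.97 (0.53-fold; log2 -0.93 ± 0.13, adjusted p = 1.3e-07, 10 of 10 mice). Changes were modest in size, with a median of 1.31-fold among genes that rose and 0.75-fold among those that fell. A log2 change beyond 0.5 was seen for 14 genes that rose and 27 that fell.

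The other large rises in KO were in Zfp395, a zinc finger protein (log2 0.66), Kcns1, a modulatory potassium channel subunit (0.62), Zak (Map3k20), a MAP kinase kinase kinase (0.61), and Plcb4, a phospholipase C (0.59). Flrt3, a leucine-rich adhesion protein, and the orphan nuclear receptor Esrrg also rose by 0.59. Irak1, a kinase of interleukin-1 and Toll-like receptor signalling, and Fam43a rose by 0.57, as did Sdk1, an immunoglobulin-family adhesion protein of synapses. Ntn5, of the netrin family, rose by 0.54 and Shroom3, an actin-binding protein, by 0.53. Their standard errors lay between 0.06 and 0.16 and their adjusted p between 1.8e-10 for Irak1 and 0.002 for Ntn5. Each was above the WT mean in 10 of 10 KO mice except Ntn5, at 9 of 10.

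Among the large falls, the cytochrome P450 gene Cyp2s1 fell from 82.5 ± 17.9 to 44.6 ± 10.5 normalized counts (log2 -0.88) and Grp, which encodes gastrin-releasing peptide, from 137 ± 13.4 to 76.7 ± 11.4 (log2 -0.84, adjusted p = 2.9e-10). Fgf11, an intracellular member of the fibroblast growth factor family, had a log2 change of -0.81, the glycine receptor subunit Glra3 -0.72, the orexin receptor Hcrtr1 -0.71 and the lectin Clec18a -0.70. The complexin Cplx3 had -0.69, the sodium channel family member Scn7a -0.68 and the secreted glycoprotein Stc1 -0.66. All of these were below the WT mean in 10 of 10 KO mice. Hcrtr1 was above background in 5 of 10 KO mice, Clec18a in 3 and Stc1 in 7, and Ntn5 in 5 of 10 KO-line WT mice, so their changes are measured partly at the floor. After quantile normalization the call of Stc1 was lost (-0.21, adjusted p = 0.17). Pappa2 was called at 12.5 ± 4.27 in KO-line WT and 7.02 ± 3.82 in KO (adjusted p = 0.0014), but it was above background in 0 libraries and no fold is given for it.

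**Figure D1:**
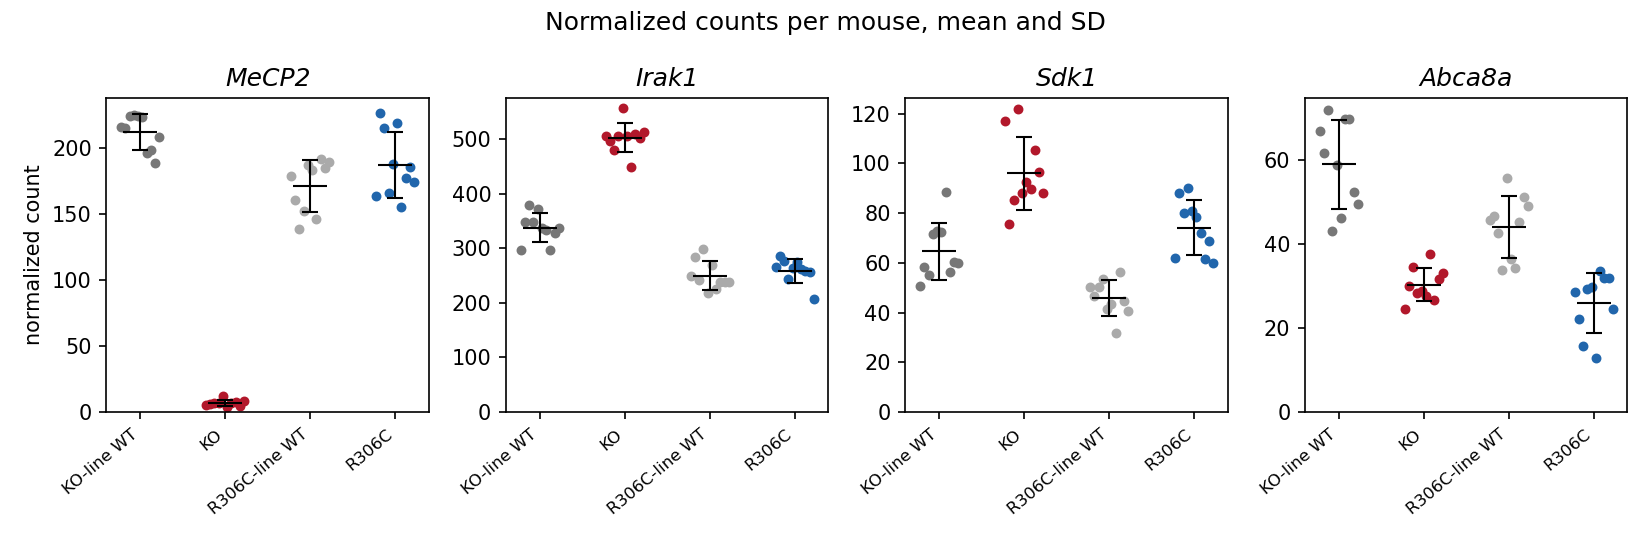
Normalized counts (vertical axis, linear) of MeCP2, Irak1, Sdk1 and Abca8a in each mouse of the 4 groups, with the mean and SD of 10 mice as black bars. MeCP2 lies between 4.14 and 12.37 in KO and at 138.61 or above in every other mouse, Irak1 is higher in KO only against its own WT, Sdk1 is higher in both mutants and Abca8a lower in both.

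By gene list, the 6 members other than MeCP2 of the fixed list of transcription and chromatin regulators rose in KO: Zfp395, Esrrg, Auts2 (0.49), Runx2 (0.46), Tshz2 and Foxo3. Transcription factors outside the fixed list did not all rise: E2f1 (-0.46) and Npas1 (-0.61), named after their values were seen, fell. The shift of the list against the rest of the panel had an adjusted p of 0.03 in camera, an adjusted p = 0.11 with an estimated correlation and 0.072 after quantile normalization. All 5 neurotransmitter receptor genes of the fixed list fell, led by Glra3, Hcrtr1, the NMDA receptor subunit Grin2d (-0.49) and the serotonin receptor Htr1a (-0.49; adjusted p = 0.03, and adjusted p = 0.082 with an estimated correlation). After quantile normalization the calls of Hcrtr1 (-0.19, adjusted p = 0.13), Grin2d (-0.25, adjusted p = 0.067) and the list (median log2 -0.34, adjusted p = 0.15) were lost. The call of the list was also lost with median centring (median log2 -0.57, adjusted p = 0.056), against a median of -0.49 with the values as given. Of 12 cell adhesion and synapse organisers 10 rose and 1 fell, with Flrt3, Sdk1, the cadherin Cdh4 (0.48) and the teneurin Tenm3 (0.46) foremost (adjusted p = 0.03, adjusted p = 0.25 with an estimated correlation and 0.15 after quantile normalization). Most adhesion genes, such as Tenm3 and Sdk1, and most of the regulators, such as Auts2 and Esrrg, span over 100 kb. Panel genes of that length mostly rose in KO, so camera cannot tell a shift of these 2 lists from one of long genes.

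Other lists went both ways in KO, and none of them shifted against the panel. Of 9 axon guidance genes 4 rose and 5 fell, including rises of Ntn5, the ephrin Efna5 (0.44) and the semaphorin Sema5a (0.42) and a fall of the Slit receptor family member Robo3 (-0.54, and -0.16 after quantile normalization, where its call was lost at an adjusted p of 0.28; adjusted p = 0.82 for the list). Of 8 ion channel genes 2 rose and 5 fell, with falls of Scn7a, the T-type calcium channel Cacna1g (-0.58) and the sodium channel beta subunit Scn3b (-0.41; adjusted p = 0.3 for the list). Of 9 signalling genes 5 rose and 4 fell, with rises of Zak (Map3k20), Plcb4 and Arhgap10 (0.39) and a fall of the neuropeptide gene Adcyap1 (-0.40; adjusted p = 0.75). Of 7 genes studied earlier in MeCP2 mutants 5 rose, Irak1, Sdk1, Auts2, Plagl1 and Cntn4, while Crh, which encodes corticotropin-releasing hormone (-0.65), and Sst fell (adjusted p = 0.25).

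Neuronal subtype markers were few. Pvalb, the parvalbumin gene of fast-spiking interneurons, rose from 2110 ± 312 to 2920 ± 334 normalized counts in KO (log2 0.47, adjusted p = 3.4e-05), whereas Crh and the somatostatin gene Sst (-0.25, adjusted p = 0.023) fell. Tbr1, a marker of deep-layer excitatory neurons, rose by 0.29 (adjusted p = 0.0032), a call lost after quantile normalization (0.08, adjusted p = 0.41). Cspg4, a marker of oligodendrocyte precursors, was at 109 ± 15.2 in KO-line WT and 96.6 ± 14.7 in KO (log2 -0.18, adjusted p = 0.14), and the result depended on the setting. Its fall passed with each sample centred on its median (-0.26, adjusted p = 0.0088), with sample weights (-0.19, adjusted p = 0.041) and in a rank-sum test (adjusted p = 0.039), but after quantile normalization its change was 0.03 (adjusted p = 0.78). None of the 5 reference genes of the fixed list was called in KO, with log2 changes from -0.11 (Csnk2a2, adjusted p = 0.055) to 0.06 (Aars), and Ccdc127 at 0.03. Their median was 0.02 and their mean -0.02 (adjusted p = 0.8), and the authors' scaling holds these genes near constant by construction. Csnk2a2 and Lars passed the test when samples were centred on the median, at -0.19 and -0.18, and after quantile normalization, at -0.21 and -0.20. Csnk2a2 also passed with the replicate number as a block (-0.11, adjusted p = 0.021), with sample weights, and when some single mice were left out.

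In R306C 75 genes rose, 69 fell and 56 were not called. Sdk1 rose most, from 45.9 ± 7.10 to 74.2 ± 11 normalized counts (1.60-fold; log2 0.68 ± 0.10 SE, adjusted p = 5.5e-07, 10 of 10 R306C mice above the WT mean). Abca8a again fell most, from 44 ± 7.37 to 26 ± 7.12 (0.58-fold; log2 -0.78 ± 0.13, adjusted p = 4.9e-06, 10 of 10 mice). The serotonin receptor gene Htr1a fell from 211 ± 22.1 to 123 ± 17.2 (0.58-fold; log2 -0.77 ± 0.07, adjusted p = 2.4e-11). The median change was 1.25-fold among genes that rose and 0.79-fold among those that fell.

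The other large rises in R306C were in Kcns1 (0.63), the transcription factor Runx2 (0.62), the presynaptic protein Rims3 (0.57), Ntn5 (0.55), Fam43a (0.54), Cdh4 (0.51), the synaptic vesicle protein Vamp1 (0.48) and Esrrg (0.48). Pvalb and the transcription factor Maf rose by 0.46, and the membrane trafficking protein Pacsin2 by 0.44. Number 3 of the R306C mice had far the highest Rims3, Cdh4 and Pacsin2, and without it their changes were 0.44, 0.42 and 0.38 and that of Vamp1 0.41, all still called. Falls besides Abca8a and Htr1a were in Grp (-0.76), Robo3 (-0.73), the lipoprotein lipase gene Lpl (-0.69), Fgf11 (-0.68), Scn7a (-0.65), Crh (-0.63), Stc1 (-0.61), the orphan receptor Gpr153 (-0.60), Glra3 (-0.59) and the cation channel Trpc6 (-0.57). Stc1 and Robo3 were each above background in 3 of 10 R306C mice, and Abca8a in 6. Ntn5 was above it in 6 of 10 R306C-line WT mice, so these changes are measured partly at the floor. The call of Stc1 was lost after quantile normalization (-0.31, adjusted p = 0.066).

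The same 6 transcription and chromatin regulators of the fixed list rose in R306C too, led by Runx2, Esrrg, Auts2 (0.42) and Zfp395 (0.35; camera adjusted p = 0.0088, and adjusted p = 0.06 with an estimated correlation). As in KO, this shift cannot be told from one of long genes. All 5 neurotransmitter receptor genes of the list fell, with Hcrtr1 at -0.44 and Grin2d at -0.35 behind Htr1a and Glra3 (adjusted p = 0.0088, and adjusted p = 0.025 with an estimated correlation). Hcrtr1 was above background in 8 of 10 R306C-line WT mice and 3 of 10 R306C mice, so its fall is measured partly at the floor. The call of Grin2d was lost without R306C replicate 10 (-0.28, adjusted p = 0.052), and after quantile normalization those of Grin2d (-0.24, adjusted p = 0.096) and Hcrtr1 (-0.15, adjusted p = 0.26) were lost. Of 12 adhesion genes 8 rose and 1 fell, including rises of Sdk1, Cdh4, Tenm3 (0.40) and Flrt3 (0.29), but the list's shift did not pass the test (adjusted p = 0.12). Of 9 axon guidance genes 3 rose and 4 fell, with rises of Efna5 (0.42) and Sema5a (0.33); the list's median was -0.05 while camera's direction was up (adjusted p = 0.99). Of 8 ion channel genes 2 rose and 4 fell, including Cacna1g (-0.43, and -0.56 without number 3; adjusted p = 0.35 for the list), and of 9 signalling genes 3 rose and 2 fell, including Plcb4 (0.37), Arhgap10 (0.25), Adcyap1 (-0.26) and Rgs19 (-0.26; adjusted p = 0.79). After quantile normalization the calls of Arhgap10 (0.09, adjusted p = 0.29) and Adcyap1 (-0.18, adjusted p = 0.096) were lost. Of 7 genes studied earlier 3 rose, Sdk1, Auts2 and Plagl1 (0.36), and Crh fell (adjusted p = 0.39).

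Pvalb (log2 0.46, adjusted p = 8.9e-05) and Tbr1 (0.28, adjusted p = 0.0059) rose in R306C, though Tbr1 by only 0.17 without number 3 (adjusted p = 0.0054), and by 0.12 after quantile normalization, where its call was lost (adjusted p = 0.21). Sst was at 1640 ± 187 in R306C-line WT and 1710 ± 576 in R306C (log2 0.01, adjusted p = 0.93), with number 3 at 3220. Cspg4 was at 93.3 ± 16.6 and 86.6 ± 26.1 (-0.14, adjusted p = 0.27), and its fall passed the test without that mouse (-0.23, adjusted p = 0.036). Of the 5 reference genes Tada2b fell by 0.12 (adjusted p = 0.047), a call lost with all 3 other scalings, with a pseudocount of 10, with each cohort fitted alone, without any 1 of several mice and when adjusted over the list alone. In each mutant the counts adjusted over the list alone equalled those over all genes for every other list.

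Within the R306C cohort, mice with numbers 1 to 6 and 7 to 10 of both genotypes formed separate sets, a split seen in the data and not in the labels. With the set as a covariate 149 genes were called in R306C, among them all 144 above. Both genotypes have the same numbers in each set, so the covariate cannot move the changes and alters only their error. Numbers 1 to 6 alone gave 60 rises and 38 falls, and numbers 7 to 10 alone gave 44 rises and 62 falls. The median change over the panel was 0.07 in the first set and -0.08 in the second. An offset of that kind tilts the balance of rises and falls, so the balance does not show a different response. The cause of the offset was not tested. Each of the 144 genes changed in the same direction in both sets. They were called from these same mice together, so this is no separate check. Changes in the sets correlated across genes at r = 0.87. Sdk1 changed by 0.73 and 0.61 in the 2 sets, Abca8a by -0.93 and -0.54, and Htr1a by -0.79 and -0.75, while Tbr1 changed by 0.38 and 0.13 and passed the test in neither set alone.

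The direct comparison of the mutants asks whether R306C changes the panel as loss of the protein does. Of the genes that rose, 73 rose in both mutants, where 35.6 were predicted for independent lists of these sizes, and 66 fell in both, where 29.3 were predicted (Fisher's exact test, one-sided, p = 6.7e-32 and 1.9e-31). No gene was called in opposite directions, and 193 of 200 had the same sign. Across genes the log2 changes correlated at Pearson's r = 0.70 and Spearman's rho = 0.88, and without MeCP2, an alternative added after the data were received, at 0.92 and 0.89. Each had the smallest p that 100 permutations can give, 0.0099, also after adjustment over these 4 correlations. Genes are not independent replicates, though Fisher's test takes them as such, so its p-values overstate the evidence. How the panel was chosen is not given, and the overlap holds for this panel only. The cohorts share no WT mice.

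The change differed between mutants for 4 genes. MeCP2 was the first, with a log2 change of -4.77 in KO and 0.13 in R306C. No KO library was above background for MeCP2, so the size of its KO change is set by the floor. Irak1 rose from 338 ± 26.8 to 503 ± 27 normalized counts in KO (1.49-fold) but was at 250 ± 26 and 259 ± 21.9 in R306C-line WT and R306C (1.04-fold; difference -0.52 ± 0.08 SE, adjusted p = 1.3e-05). The zinc finger gene Zkscan16 rose from 445 ± 37.8 to 598 ± 44.8 in KO and was at 490 ± 63.4 and 493 ± 47.5 in the R306C cohort (difference -0.42 ± 0.09, adjusted p = 0.0049). Trpc6 fell from 95 ± 10 to 63.9 ± 8.23 in R306C and had a log2 change of -0.14 in KO (adjusted p = 0.11; difference -0.43 ± 0.12, adjusted p = 0.039). With samples centred on the median, Zkscan16 (-0.34, adjusted p = 0.087) and Trpc6 (-0.36, adjusted p = 0.097) were not called and Cyp2s1 and Gdf11 were. Gdf11 was also called with the replicate block (0.34, adjusted p = 0.035). Cyp2s1 was also called with the set of R306C-cohort replicates as a covariate (0.59, adjusted p = 0.046). The call of Trpc6 was also lost in 20 of the 40 fits that leave out 1 mouse, while its difference stayed between -0.47 and -0.38.

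A further 38 genes called only in KO and 4 called only in R306C showed no tested difference between mutants, for example Zak (Map3k20) at 0.61 in KO and 0.19 in R306C (adjusted p = 0.11 for the difference) and Sst at -0.25 and 0.01 (adjusted p = 0.4). No list differed between mutants in camera, the lowest adjusted p being 0.23 for adhesion genes. Adjusted over the list alone, the difference passed for Cntn4 and Flrt3 among adhesion genes, Htr1a among receptors, Zak (Map3k20) among signalling genes, Trpc6 among channels, and Irak1 and Cntn4 among genes studied earlier.

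**Figure D2:**
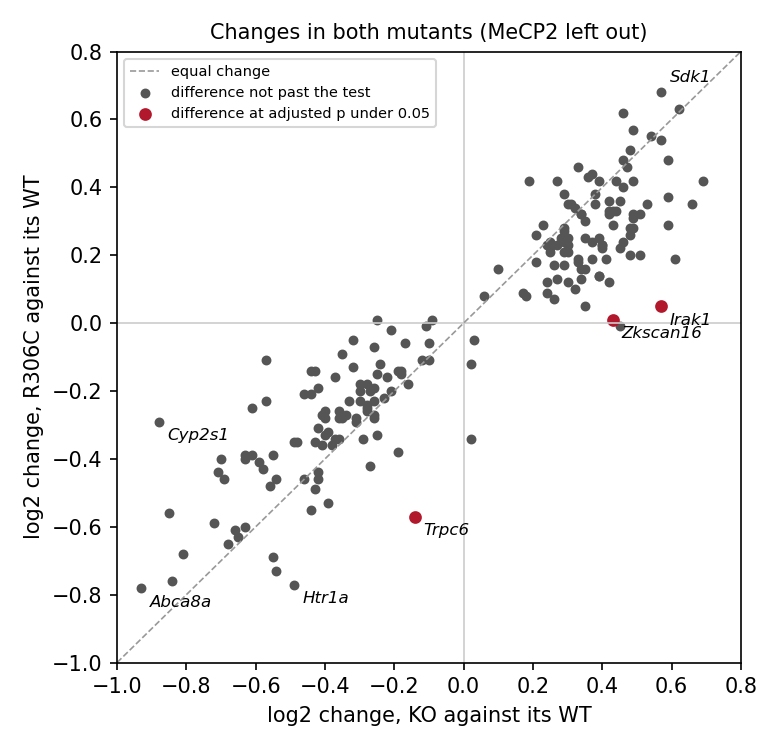
Log2 change of 199 genes in KO (horizontal axis) and in R306C (vertical axis), each against its own WT, with MeCP2 left out and the dashed line marking equal change. The changes correlate (Pearson's r = 0.92), but of 139 genes called in both mutants 108 changed less in R306C than in KO. Irak1, Zkscan16 and Trpc6, in red, differ between mutants at an adjusted p under 0.05.

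The series' title names long genes, so changes were set against gene length for 197 genes spanning 1.77 to 1300 kb. Of 66 genes longer than 100 kb, 55 rose and 8 fell in KO, including rises of Tenm3, Auts2, Sdk1 and Esrrg, while Scn7a and Glra3 fell. Of the 131 shorter genes 40 rose and 74 fell, with Irak1, Fam43a and Kcns1 among the short genes that rose. In R306C 45 long genes rose and 8 fell, against 30 and 59 of the shorter genes. The median log2 change of long and shorter genes was 0.34 and -0.26 in KO and 0.23 and -0.18 in R306C (camera p = 1.2e-09 and 5.4e-08, and p = 0.0036 and 0.0091 with an estimated correlation). Genes that rose had a median length of 152 kb in both mutants, and genes that fell 21.3 kb in KO and 22.4 kb in R306C. How the panel was chosen is not given. If long genes that rise and short genes that fall were picked for it, this split would follow from that choice. It therefore holds for this panel only.

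Spearman's rho of change with length was 0.47 in KO and 0.42 in R306C, and neither exceeded the planned permutations of genotype labels (p = 0.1485 and 0.1683, adjusted p = 0.1683 for both). Permuted labels carry part of the genotype effect, and absolute rho under them reached 0.50 and 0.53. With residuals permuted instead, chosen after seeing the data, absolute rho reached 0.22 and 0.40 and p was 0.0099 for both, the smallest possible.

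**Figure D3:**
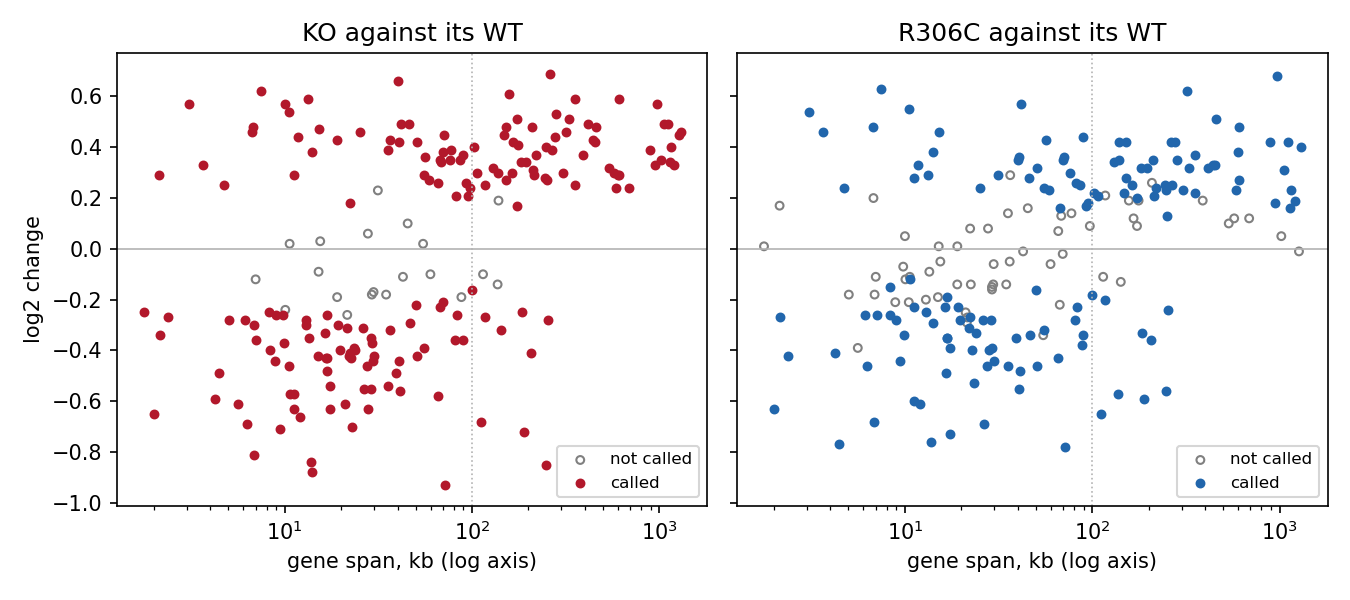
Log2 change (vertical axis) against gene span in kb (horizontal log axis) for 197 genes in KO (left) and R306C (right), with called genes filled and the dotted line at 100 kb. Most genes to the right of the line rose, 55 of 66 in KO and 45 of 66 in R306C.

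As a check, the WT groups were set against each other. R306C-line WT was lower for 127 genes and higher for 0 (limma; 132 genes at an unadjusted p under 0.05), with a median log2 difference of -0.25, which holds the scale difference of -0.30 between cohorts. With median centring 12 genes were higher and 12 lower, with quantile normalization 10 and 10, and with reference gene centring 19 and 10. On a common scale of the 6 reference genes, an alternative chosen after seeing the data, 25 genes were higher and 9 lower. Named after their values were seen, Zkscan16 was higher by 0.43 and Cirbp, a cold-inducible RNA-binding protein, by 0.47, and the growth factor gene Gdf11 differed by -0.33. Aars (0.35) and Lars (-0.23), both used for the scaling, also differed. Line, age and cohort go together here and cannot be told apart.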

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

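The Irak1 ratio test, the signed test of its neighbours and the spike-in tests below were chosen after the result was seen, and the other tests before. In 236 sets of 10 values, 25 had a mouse far from the rest by Dixon's test, where chance gives about 1 in 20, or 11.8, and 14 of the 25 were in R306C replicate 3.

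The change of Irak1 differed between mutants by -0.52, which did not rest on 1 library or on the scaling, since the highest adjusted p over all settings was 0.00017. Its R306C change was 0.09 of its KO change, but Irak1 was picked for this contrast, so the ratio does not decide whether it follows loss of MeCP2 function as other genes do. Irak1 is the nearest protein-coding neighbour of Mecp2 on chromosome X, and a local effect of the targeted allele may contribute. Plxna3 and Pls3, the other panel genes within 5 Mb, differed by 0.10 (SE 0.14) and 0.03 (SE 0.11) and fell in KO by 0.33 and 0.36. The bound set beforehand ignored sign and was not met, but the lowest signed difference less 2 SE was -0.19, which argues against a change like that of Irak1 and of 0.26 or more in size reaching both; an effect confined to Irak1, line and age stay open.

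R306C replicate 3 was far above the other R306C mice for Scn3b (1890, others 954 to 1060), Tbr1 (1040, others 450 to 541), Pacsin2 (1100), Tenm3 (1420), Cacna1g (352), Cdh4 (420), Rims3 (479), Csnk2a2 (1040), Sst (3220), Auts2 (1080), Fgf11 (64.2) and Cplx3 (123), and below them for Zak (Map3k20) (37.9). Its strongest positive control stood at 4.96 above the mean of the positive controls on the log2 scale, against 4.33 to 4.48 in the other R306C mice (Dixon's ratio 0.75), and since spike-ins do not come from the mouse, a difference in hybridisation or lane is a candidate explanation. A constant scale difference alone is argued against. After centring on the median, the median absolute departure of this library was still 2.38 times that of the other R306C mice. The values were already scaled per library, so this test cannot decide on an effect of depth that varies by gene. This library had the highest depth of the R306C cohort (142994) and the lowest background of all 40 (7.2). No biological explanation was tested, and a difference in dissection stays open.

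In the R306C cohort 86 genes differed between numbers 1 to 6 and 7 to 10 across both genotypes, 73 of them lower in the later numbers, such as Cdk18 (-0.39) and Chst8 (-0.42). Aars, one of the 6 genes used for the scaling, was also lower (-0.27). The sets were not compared with another scaling, so the one-sided count may hold an offset from the scaling. The cut between these sets was found in the same data, so this count restates the split and was not set against other cuts. A difference in depth is argued against, since 96 genes differed with log2 depth as a covariate, and so is R306C replicate 3, since 94 differed without it. The strongest positive control differed by -0.06 between sets (permutation p = 0.492), which leaves a hybridisation difference open. The labels give ages of 8 to 12 weeks for this cohort without dividing it, so an age or batch difference may be the source and stays untested.

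Other values far from their group were Zfp395 (77.3) and Zak (Map3k20) (152) in KO replicate 6, Auts2 (1010) and Gpr153 (219) in KO replicate 7, and Crh in KO replicate 4 (64.0) and KO-line WT replicate 9 (178). Fgf11 was at 44.3 in KO-line WT replicate 7, Plcb4 at 692 in R306C-line WT replicate 5, Ccdc127 at 1040 in R306C-line WT replicate 10, and Irak1 (206) and Stc1 (34.7) stood apart in R306C replicate 10. Over the panel, R306C replicate 10 had a median absolute departure of 0.28, and 0.20 after median centring. Both were the largest of any library after R306C replicate 3 (0.33 and 0.31). Besides Irak1, the change differed between mutants for MeCP2 (4.90, with KO at the floor), Trpc6 (-0.43) and Zkscan16 (-0.42).

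Chance division of the libraries was tested with 100 splits, the real one included. For KO 1 split, the real one, gave as many as 180 genes (highest other 104), and for R306C 1 gave 144 (highest other 60). No other split drawn reached these counts, which is the lowest share that 100 splits can give. For the WT groups 1 split gave 127 (highest other 29). That count holds the scale difference between cohorts, so the splits cannot tell chance from that scale. For the difference between mutants the real count includes MeCP2, which the KO removes, so the splits do not test the other called genes alone. Here 4 splits gave 4 genes or more, a share under 0.05, but the highest other gave 26, several times the real count. Such a split points to structure among the libraries, which could include the genotype effect that uneven splits still carry, and its cause was not tested.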

How the results depend on the processing

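Alternatives were fixed before the data were examined, except those named as chosen after and those the methods name as added. The counts of called genes ran from 162 to 189 in KO and from 113 to 159 in R306C over the planned settings, and with 1 mouse left out from 176 to 184 in KO and from 131 to 154 in R306C. The 162 came from the filter on genes with low means, which tests fewer genes, and the 113 from an adjusted p under 0.01. Quantile normalization kept 156 of the 180 KO calls and 110 of the 144 R306C calls. The correlation of changes was 0.67 to 0.75 and Spearman's rho 0.87 to 0.90, and with 1 mouse left out 0.69 to 0.71 and 0.87 to 0.89. Rho of change with length ran from 0.45 to 0.48 in KO and from 0.40 to 0.43 in R306C with 1 mouse left out. It stayed short of the threshold under every planned setting and passed it only with residuals permuted, chosen after seeing the data, where rho was 0.47 in KO and 0.42 in R306C by construction. The count of genes that differ between WT groups fell from 127 to 24 with median centring, 29 with reference gene centring, 20 with quantile normalization and, chosen after seeing the data, 34 with cohorts on a common scale, because these remove the offset between cohorts. It ran from 114 to 137 with 1 mouse left out. The count of differences between mutants ran from 3 to 7 with 1 mouse left out, and the 7 genes came without R306C replicate 10, which added Cyp2s1, Gdf11 and Zak (Map3k20); the cause was not tested. Of 5088 recomputed values for named genes and lists, 76 lost their call, 20 gained one and 0 passed the test in the opposite direction. Quantile normalization cost most calls of named genes: Hcrtr1 (-0.19 in KO, -0.15 in R306C), Stc1 (-0.21, -0.31), Grin2d (-0.25, -0.24) and Tbr1 (0.08, 0.12) in both mutants, Robo3 (-0.16) and Pappa2 in KO, and Adcyap1 (-0.18), Arhgap10 (0.09) and Tada2b in R306C. Lists lost their call in KO with quantile normalization, at an adjusted p of 0.15 for adhesion genes, 0.15 for receptors and 0.072 for transcription regulators, and receptors also with median centring (0.056). With an estimated correlation the calls of adhesion genes (0.25), receptors (0.082) and transcription regulators (0.11) in KO and of transcription regulators in R306C (0.06) were lost. The median change of genes over the length limit was 0.32 in KO and 0.22 in R306C at 60 kb. The labels do not pair the mice, but same-numbered WT and mutant mice resembled each other more than others did: their residuals correlated at a mean of 0.23 (0.02 to 0.35) in the KO cohort and 0.19 (0 to 0.52) in the R306C cohort, against -0.02 for other numbers in both, and 12 and 5 of 20 mice correlated best with their own number. The division into sets may add to this in the R306C cohort, but the cause was not tested. With the replicate block 181 genes were called in KO, 152 in R306C and 5 in the difference, and no direction changed. The planned count test was not run, because the table holds scaled gene values beside raw control probes. Depth limits most the 7 genes above background in fewer than 20 libraries.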

Other observations

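The amplitude test was chosen after changes in both mutants had been seen, and the length test before its result was seen. Of genes outside the naming rule, named here after their values were seen, Npas1 and Cirbp were called in KO and had the same sign in R306C without passing the test there. Npas1, a transcription factor of interneurons, changed by -0.61 in KO and -0.25 in R306C, and Cirbp, a cold-inducible RNA-binding protein, by 0.48 and 0.20 (adjusted p = 0.058 and 0.098 in R306C). The contactin Cntn5 was at 0.45 in KO and -0.01 in R306C, a difference that passed the test after quantile normalization (adjusted p = 0.045) but not with the values as given (adjusted p = 0.21). Fcrls, a microglial gene outside the fixed lists, fell by 0.28 in KO (adjusted p = 0.0034) and by 0.25 in R306C (adjusted p = 0.012).

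Zkscan16 combined a rise in KO of 0.43 with a WT difference of 0.43 between lines on the common reference scale (adjusted p = 1.5e-05), so that KO-line WT was the lowest of the 4 groups on that scale. The difference between mutants and the difference between WT groups share the WT libraries and are not independent.

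A hypothesis is that R306C changes the same genes by a smaller amount. Over 198 genes, MeCP2 and Irak1 left out, the root mean square change corrected for error was 0.41 ± 0.01 in KO and 0.32 ± 0.01 in R306C (jackknife SE), a ratio of 0.78 ± 0.04, and the corrected correlation was 1 ± 0.02. Of 139 genes called in both mutants, 108 had the smaller absolute change in R306C. The ratio stayed between 0.77 and 0.80 when any 1 mouse was left out. A partial loss of function may give such a pattern, but line, age and cohort differ in the same way and cannot be told apart from it.

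A further hypothesis was that change rises with length also among genes longer than 100 kb. Among 66 such genes Spearman's rho was 0.36 in KO (permutation p = 0.0891) and 0.24 in R306C (permutation p = 0.2574), so the hypothesis was not borne out by the planned test. With residuals permuted p was 0.0099 in KO and 0.1188 in R306C.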
